A study of Mus musculus with 14 samples.

How the data were processed

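The series holds 6 RNA libraries and 4 H3K27ac libraries of Y1 cells, 3 and 2 per group, with 4 input libraries that were used here only as the background of the authors' peak lists. Groups were taken from the treatment labels. The submitters' processing notes name bcl2fastq, STAR 2.5.2a, SAMtools 1.1, bedtools 2.15.0, MACS2 2.2.6, DiffBind, ChIPseeker, HTSeq 0.10.0 and DESeq2, and the mouse build mm10.

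RNA values are raw read counts per gene symbol that the authors deposited as output of HTSeq, per their description of the files. The annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain. Reads outside genes or in more than 1 gene made up 37% to 43.2% of each library's listed reads and were left out of library sizes. A count of 0 allowed up to 0.236 to 0.533 CPM (3 counts of the library total), for counting error only. Symbols of 99.7% of the tested genes matched a RefSeq gene table, which gave positions and current names. The authors' deposited DESeq2 table gives log2 fold changes, p-values and a base mean signal, per the file headers. Rerunning DESeq2 on the counts gave its log2 fold changes within 1.62e-10.

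Peaks were called per library with MACS2 against that library's own input, on paired-end fragments, per the file headers, which give fold (a ratio of pileup signal over background) and −log10 q and p per peak, all values of the authors. The ChIP libraries had 11840994 to 14156846 fragments and the inputs 12241177 to 110273836, the most for serum library 2. The authors' deposited region table gives log2 folds, p-values, false discovery rates and a signal per library. From their values, these signals were taken as whole reads with a floor of 1 read, divided by a factor per library. That input reads were subtracted first, as DiffBind can do, is not stated in the sources used here. With factors estimated from the values, 99.9%, 99.9%, 99.9% and 100% of values came out whole within 0.02 reads. The reads in regions were 35.3% and 28% of fragments for serum alone and 34.1% and 34.6% for FGF-2. The region table's own test could not be rebuilt from its labels, so its calls are given as deposited.

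The RNA test was edgeR 4.0.16 (quasi-likelihood, robust, TMM, filterByExpr by group) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. SEs were computed as the absolute log2 fold change over the square root of F. CPM per library used TMM factors. Gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. Of 29 lists, 26 with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. DESeq2 1.42.0 and limma-voom were alternatives. Figures and peak overlaps used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

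The rule for named genes took the 10 largest increases and 10 largest decreases at a mean of at least 5 CPM with no overlap between groups, up to 2 members each way per list, 10 genes named in advance, the 5 largest region changes each way, up to 4 members with a called region in each of 3 lists, and the 6 genes of smallest p called the same way in both assays, with up to 4 called in opposite ways. The genes given for serum library 3 (Dll4, Il11, Inhba and Star) were singled out after their values were seen. So were Txnip, Sesn1 and the members named of the BMP-SMAD and FOXO lists. Some genes that the rule takes are not reported here.

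Merged peak regions were compared by an overlap of at least 1 base. RNA and region calls were joined by symbol or Entrez number: 30449 of 40772 regions (74.7%) were tied to a tested gene. Overlaps were tested with Fisher's exact test and correlations with 100000 permutations. Replicate libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.06 to 24.0, so each was kept as a library of its own.

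The RNA and H3K27ac tests were run first on simulated data with 200 changed genes. At these depths edgeR recovered 81% of 2-fold and 95% of 4-fold RNA changes over 10242 genes, with 19 unchanged genes called. For H3K27ac with 2 libraries per group, it recovered 15% of 2-fold and 72% of 4-fold changes over 40772 regions, with 4 unchanged regions called. With no simulated RNA change 1 of 10240 genes was called.

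The settings fixed in advance covered the tool, scaling, low-count filter, thresholds, replicate block, left-out libraries, peak threshold and overlap. Those chosen after seeing the data were upper-quartile and library-total scaling of RNA, the tests on recovered H3K27ac reads, the counts of list members without single RNA libraries, and leaving out floored regions, regions of high input background or single H3K27ac libraries.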

Results

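Y1 is a mouse adrenocortical tumour cell line. The cells were starved of serum for 48 h and then given 10% fetal bovine serum, either alone or together with 10 ng/ml fibroblast growth factor 2 (FGF-2), and were collected after 5 h. Polyadenylated RNA was sequenced in 3 libraries per group. Chromatin carrying acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was sequenced in 2 libraries per group, each with its own input library. The RNA libraries held 9101089, 8159993 and 5625004 counts in genes for serum alone and 11272041, 12696426 and 6403095 for serum with FGF-2. The H3K27ac libraries held 12856806 and 14156846 fragments for serum alone and 12447135 and 11840994 for serum with FGF-2. The comparison asks how 5 h of FGF-2 on top of serum changed transcript levels and H3K27ac. Values per library are given as mean ± SD of normalised CPM (counts scaled to a common library size, n = 3 per group), and log2 fold changes are serum with FGF-2 over serum alone with the standard error (SE).

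With FGF-2, 13 of 18 measured secreted ligands and 12 of 15 feedback regulators of ERK signalling rose, and 26 of 28 mitotic genes fell. None of these lists stood apart from other genes in camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.481, 0.24 and 0.481). Il11, a cytokine of the interleukin 6 family, rose from 10.7 ± 11.3 to 807 ± 189 CPM. Dusp4 and Dusp5, which encode phosphatases of MAP kinases, had log2 fold changes of 4.64 ± 0.43 and 4.84 ± 0.44. Star, which encodes the protein that moves cholesterol into mitochondria for steroid synthesis, rose from 165 ± 101 to 2296 ± 764 CPM. Bub1b, a spindle checkpoint kinase, fell from 58.2 ± 11.7 to 15.6 ± 3.59 CPM. Without serum library 3 the log2 fold changes of Il11, Dusp4 and Star were 7.58, 5.28 and 4.42 in place of 6.35, 4.64 and 3.80. Of 10374 genes tested with the edgeR quasi-likelihood test, 2295 rose and 2512 fell at a Benjamini-Hochberg false discovery rate of 0.05, and 707 and 940 of these changed by at least 1 on the log2 scale.

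**Figure D1:**
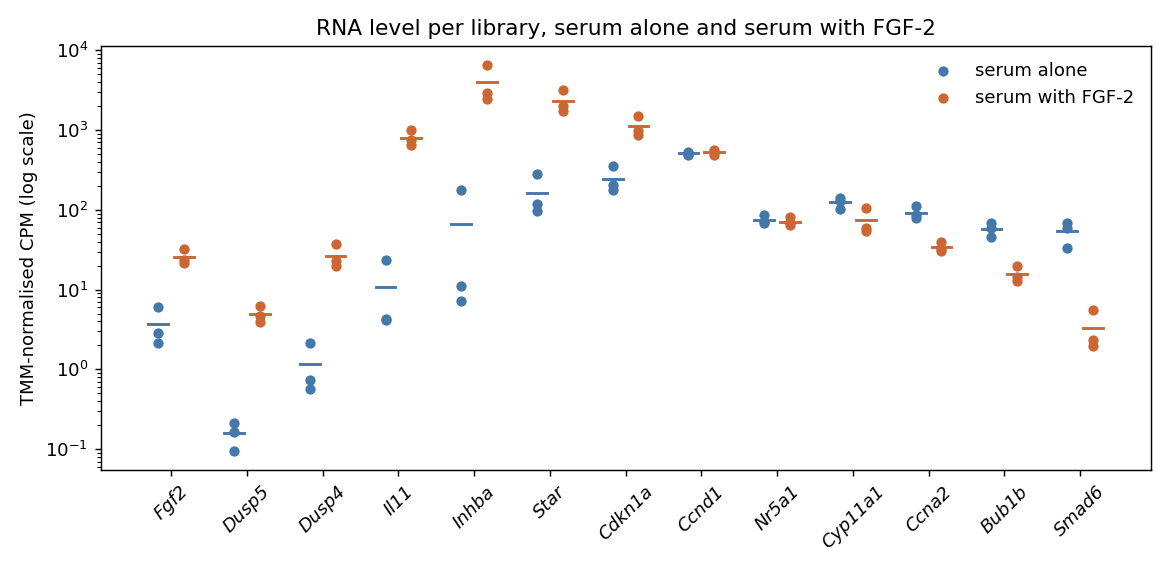
Normalised RNA level of 13 genes in each library, in TMM-normalised CPM on a log axis, with serum alone in blue and serum with FGF-2 in orange. Points are single libraries and short lines are the mean of 3. Il11 had means of 10.7 and 807 CPM, while Ccnd1 had means of 510 and 530 CPM.

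Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest increases included Crhr2, a receptor for corticotropin-releasing hormone family peptides, which rose from 2.74 ± 1.39 to 278 ± 69.3 CPM. Dll4, a Notch ligand, rose from 0.674 ± 0.603 to 77.7 ± 9.81 CPM. Osbpl6 rose from 2.37 ± 2.27 to 107 ± 58.4 CPM and Tmem204 from 0.178 ± 0.133 to 10.6 ± 5.29 CPM. Prdm1, a transcriptional repressor, had 0 counts over the serum libraries and 388 over the FGF-2 libraries, at least 123-fold higher against a floor of 3 counts over the group. Muc5ac, a secreted mucin, had 1 count against 346, a ratio of 330 with an exact 95% counting interval of 58.9 to 13087. The largest decreases included Smad6, an inhibitor of BMP signalling, which fell from 53.9 ± 18.3 to 3.30 ± 1.97 CPM, and the transcription factor Atoh8, which fell from 21.3 ± 7.24 to 1.32 ± 0.54 CPM. Ccdc114, Fam65b (now Ripor2), Cyp26b1, Ldb3, Akap6, Pde5a, Neurl1b and Fam46b (now Tent5b) fell by log2 values between -3.78 and -3.08. Cyp26b1, which degrades retinoic acid, went from 48.9 ± 15.3 to 3.96 ± 0.21 CPM, and Pde5a, a cyclic GMP phosphodiesterase, from 40.5 ± 3.29 to 4.63 ± 0.24 CPM. The only serum count of Muc5ac was in serum library 3, and its fitted log2 fold change of 8.01, which at such counts depends on the prior count, was 9.99 without that library and 7.41 without serum library 1. Single libraries moved other log2 fold changes: Osbpl6 went from 5.68 to 6.62 without serum library 3, Dll4 from 6.94 to 6.30 without serum library 2, Smad6 from -3.94 to -4.61 without FGF-2 library 2 and Ccdc114 from -3.78 to -4.89 without FGF-2 library 3.

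Of 15 measured feedback regulators of the ERK pathway and ETS targets, 12 rose and 0 fell, and the same numbers held adjusted over the list alone. Their median log2 fold change was 2.26, and the list ranked above other genes in camera with a preset correlation (Benjamini-Hochberg adjusted p = 2.81e-14, but adjusted p = 0.24 with an estimated correlation). Spred2, an inhibitor of the RAS-ERK pathway, rose from 60.8 ± 8.32 to 351 ± 36.1 CPM. Of 24 immediate-early genes, 16 rose and 1 fell, also adjusted over the list alone, with a median of 1.27 (camera Benjamini-Hochberg adjusted p = 6.19e-07, and adjusted p = 0.481 with an estimated correlation). Arc and Ier3 had the largest increases, with log2 fold changes of 4.88 ± 0.60 (4.27 without serum library 1 and 5.61 without serum library 3 for Arc) and 3.35 ± 0.20, while Fosl2, an AP-1 subunit, fell from 352 ± 23 to 171 ± 4.79 CPM. Myc rose by less, from 180 ± 8.36 to 245 ± 11.8 CPM (edgeR Benjamini-Hochberg adjusted p = 0.0053). With library totals as the only scaling, the log2 fold change of Myc was 0.11 and no longer passed. Of 10 dual-specificity phosphatases, 6 rose and 3 fell, and 6 and 4 did adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0197, and adjusted p = 0.594 with an estimated correlation). Dusp1 was among those that fell, from 45.8 ± 7.71 to 11.9 ± 0.34 CPM. The phosphatase list shares members with the ERK feedback regulators, among them Dusp4 and Dusp5, so these lists are not separate results. Without serum library 1 or 2, 4 phosphatases rose and 3 fell.

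Of 18 measured growth factors and secreted ligands, 13 rose and 0 fell, and 13 and 1 did adjusted over the list alone. Their median was 2.16 (camera Benjamini-Hochberg adjusted p = 5.9e-06, and adjusted p = 0.481 with an estimated correlation). Fgf2 itself rose from 3.71 ± 2.14 to 25.7 ± 5.59 CPM. Inhba, the activin beta A subunit, went from 65.8 ± 98.3 to 3967 ± 2225 CPM (edgeR Benjamini-Hochberg adjusted p = 0.0298), a call that was lost without serum library 2, FGF-2 library 1 or FGF-2 library 3 and with no filter on low counts. Its log2 fold change of 5.94 lay between 5.39 and 6.11 in those settings and was 8.77 without serum library 3. The adjusted p for Inhba lay between 5.54e-05 and 0.0909 over the other tools, filters, scalings and left-out libraries fixed in advance, which included edgeR, DESeq2 and limma with Benjamini-Hochberg adjustment. Of 16 secreted inflammatory and protease genes of the senescence-associated type, 8 rose and 2 fell, and 10 and 2 did adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.0197, and adjusted p = 0.594 with an estimated correlation). Ptgs2, which encodes cyclooxygenase 2, rose from 3.38 ± 4.71 to 166 ± 99.5 CPM, and the collagenase gene Mmp13 from 0.348 ± 0.431 to 14.6 ± 10.3 CPM. Their log2 fold changes of 5.90 and 5.59 were 7.94 and 6.92 without serum library 3 and 5.22 and 4.87 without serum library 1, and that of Mmp13 was 4.90 without FGF-2 library 3. The chemokine gene Ccl7 fell from 18.5 ± 1.75 to 11.5 ± 2.39 CPM, a call lost without serum library 2. The list then had 0 members that fell, and 1 without serum library 1 or FGF-2 library 1. Of 8 cAMP-CREB targets, 4 rose and 0 fell, also adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.00133, and adjusted p = 0.587 with an estimated correlation). These included Gem, with 6.83 ± 0.49 and 137 ± 60.6 CPM, and the kinase gene Sik1, with 24.3 ± 1.84 and 187 ± 36.3 CPM.

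Of 28 genes of G2/M and mitosis, 26 fell and 0 rose, also adjusted over the list alone, with a median of -1.20 (camera Benjamini-Hochberg adjusted p = 5.47e-16, and adjusted p = 0.481 with an estimated correlation). Cdc25c, a phosphatase that activates CDK1, fell from 8.61 ± 2.74 to 2.51 ± 0.50 CPM. Of 29 genes of G1/S and DNA replication, 17 fell and 1 rose, also adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.000515, and adjusted p = 0.594 with an estimated correlation). Ccna2 fell from 92.4 ± 17.3 to 34.1 ± 5.10 CPM and Cdc6, which loads the replicative helicase, from 29.5 ± 8.15 to 9.60 ± 0.87 CPM, while E2f3 rose from 63.9 ± 3.51 to 83.1 ± 3.54 CPM. E2f3 no longer passed without serum library 1 or with either upper-quartile or library-total scaling. Of the G1/S genes, 12 fell without serum library 1 or FGF-2 library 1 and 13 without serum library 2. Of 23 genes of the DNA damage and replication stress response, 17 fell and 1 rose, also adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 6.47e-06, and adjusted p = 0.481 with an estimated correlation). Brca2 and Clspn fell by log2 values of -1.79 ± 0.15 and -1.65 ± 0.14. Of 9 D cyclins and CDK inhibitors, 5 fell and 1 rose, also adjusted over the list alone, and the list did not pass (camera Benjamini-Hochberg adjusted p = 0.112). Cdkn1a, the CDK inhibitor p21, rose from 246 ± 98 to 1118 ± 348 CPM, and Ccnd1 had 510 ± 20 and 530 ± 43.5 CPM (edgeR Benjamini-Hochberg adjusted p = 0.716). The log2 fold change of Ccnd1 was 0.056 with TMM scaling, -0.084 with upper-quartile scaling and -0.28 with library totals alone, and it passed in none of the 3.

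**Figure D2:**
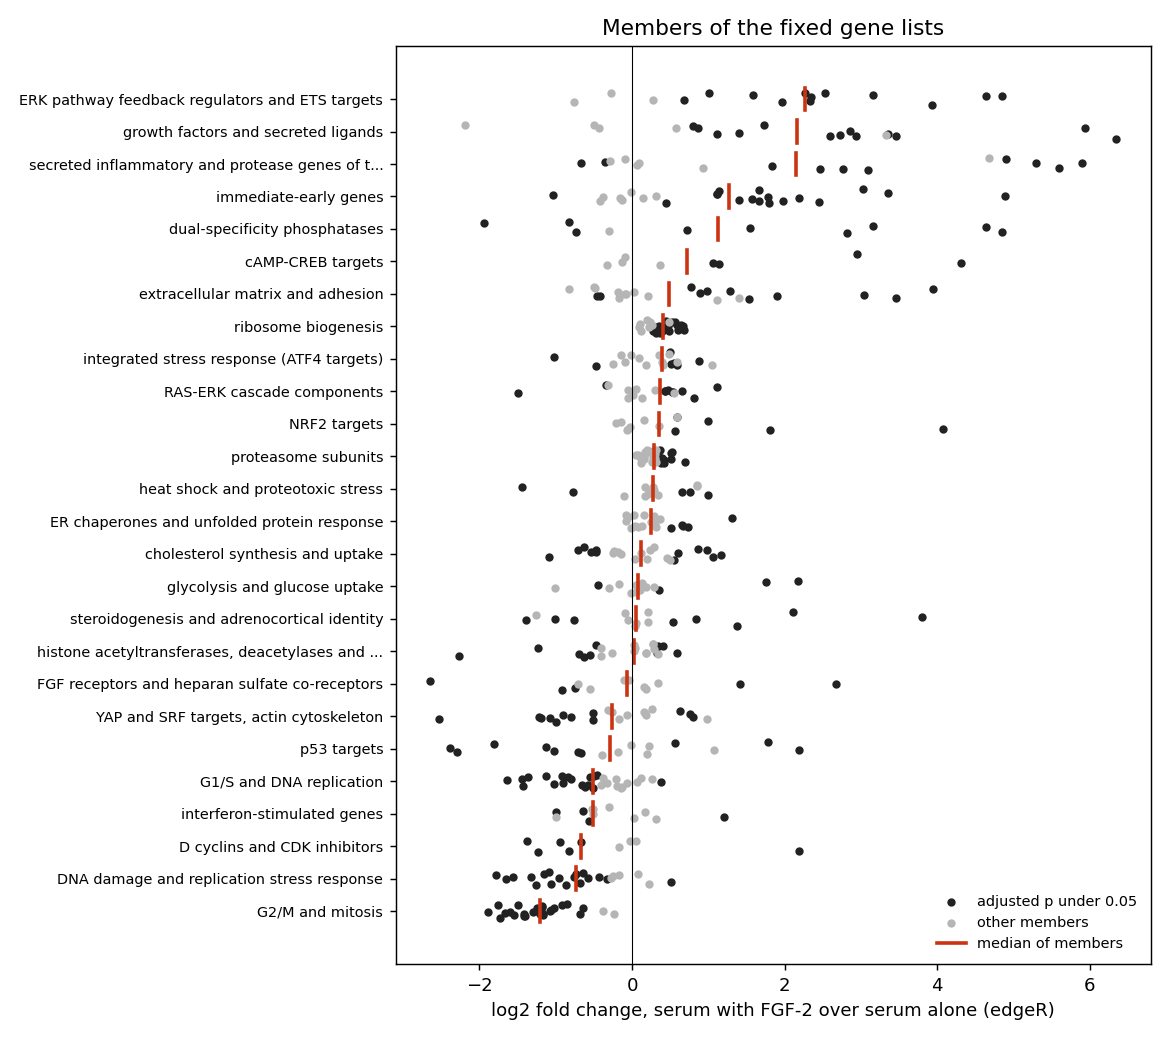
Log2 fold change in edgeR of each measured member of 26 gene lists, ordered by the median of the members. Black points passed an adjusted p of 0.05, grey points did not, and red bars mark medians. The median was 2.26 for feedback regulators of the ERK pathway and -1.20 for genes of G2/M and mitosis.

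The genes of steroidogenesis and adrenocortical identity went both ways. Of 15 measured, 5 rose and 3 fell, and 5 and 4 did adjusted over the list alone, and the list did not pass (camera Benjamini-Hochberg adjusted p = 0.35), with a median of 0.055 that became -0.085 with upper-quartile scaling and -0.29 with library totals alone. Besides Star, Soat1, which esterifies cholesterol, rose from 605 ± 203 to 2617 ± 593 CPM. Cyp11b1 fell from 9.24 ± 4.11 to 3.45 ± 0.34 CPM and Fdxr, the ferredoxin reductase gene of mitochondrial P450 enzymes, from 177 ± 15.1 to 87.4 ± 4.83 CPM. Cyp11a1, the side-chain cleavage enzyme, had a log2 fold change of -0.76 ± 0.26 (edgeR Benjamini-Hochberg adjusted p = 0.0454), and its call was lost without serum library 1 or 3 or FGF-2 library 1 or 2 and with no filter on low counts. Over all 12 other settings fixed in advance its log2 fold change lay between -1.11 and -0.58. The call held in 7 of them, including the replicate block (edgeR Benjamini-Hochberg adjusted p = 0.00202). Nr5a1, the steroidogenic factor 1 gene, had 74.3 ± 9.34 and 71.3 ± 9.80 CPM and did not pass (edgeR Benjamini-Hochberg adjusted p = 0.745). With library totals alone its log2 fold change was -0.40 and passed, but the median of all tested genes was then -0.36. Of 12 FGF receptors and co-receptors, 2 rose and 3 fell, also adjusted over the list alone, and the list did not pass (camera Benjamini-Hochberg adjusted p = 0.938), with a median of -0.071 and a mean of -0.080 although the direction of the camera test was up. The heparan sulfate proteoglycan genes Sdc1 and Sdc4 rose, with log2 fold changes of 2.67 ± 0.28 and 1.41 ± 0.19, and Fgfr4 fell from 4.42 ± 0.98 to 0.701 ± 0.107 CPM. Fgfr1 had 188 ± 8.12 and 213 ± 14.8 CPM, and Fgfr2 had 1.68 ± 0.56 and 0.930 ± 0.413 CPM, and neither passed the test. The log2 fold change of Fgfr1 was 0.18 and turned to -0.16 with library totals alone, also without passing. Of 18 components of the RAS-ERK cascade, 8 rose and 2 fell, and 9 and 2 did adjusted over the list alone, but 3 rose and 5 fell with library totals as the only scaling, and 1 fell without serum library 1 or 2 or FGF-2 library 2 or 3 (camera Benjamini-Hochberg adjusted p = 0.108 in TMM scaling).

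Of 31 ribosome biogenesis genes, 23 rose and 0 fell, and 24 rose adjusted over the list alone, with a median of 0.41 (camera Benjamini-Hochberg adjusted p = 0.000529, and adjusted p = 0.594 with an estimated correlation). Of 31 proteasome subunits, 11 rose and 0 fell, and 8 rose adjusted over the list alone, with a median of 0.28 (camera Benjamini-Hochberg adjusted p = 0.0111, and adjusted p = 0.594 with an estimated correlation). With library totals as the only scaling, 1 ribosome biogenesis gene and 1 proteasome subunit rose, and the medians were 0.064 and -0.059. With upper-quartile scaling 10 and 3 rose. Single libraries also set these counts: 15 and 9 ribosome biogenesis genes rose without serum library 1 and serum library 2, and 3, 7, 7 and 5 proteasome subunits rose without serum library 2, serum library 3, FGF-2 library 1 and FGF-2 library 3. Rrp9 and Psmd11 had the largest increases of their lists, with log2 fold changes of 0.68 ± 0.11 and 0.69 ± 0.12.

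The groups of libraries did not overlap for 57.5% of the tested genes, where chance gives 10%, and the first principal component, which separated the groups, held 79.5% of the variance. Serum library 3 lay nearest to the FGF-2 libraries, and without it 2417 genes rose and 2540 fell, and the members that rose or fell were 12 and 1 for ERK feedback regulators, 16 and 1 for immediate-early genes, 15 and 1 for growth factors, 9 and 2 for senescence-type genes, 5 and 0 for cAMP-CREB targets, 20 and 0 for ribosome biogenesis, 7 and 0 for proteasome subunits, 0 and 26 for G2/M genes, 1 and 19 for G1/S genes and 1 and 17 for DNA damage genes. FGF-2 library 3 stood apart from the other FGF-2 libraries on the second component, and without it 2161 genes rose and 2370 fell, with 12 and 0 for ERK feedback regulators, 16 and 1 for immediate-early genes, 12 and 0 for growth factors, 8 and 2 for senescence-type genes, 4 and 1 for cAMP-CREB targets, 22 and 0 for ribosome biogenesis, 0 and 26 for G2/M genes, 1 and 16 for G1/S genes and 1 and 16 for DNA damage genes. Before TMM scaling, Il11 stood at 25.4 CPM in serum library 3 and at 4.72 and 4.90 CPM in the other serum libraries. Markers of fibroblasts and adrenal capsule summed to 270 ± 62.1 CPM with serum alone and 202 ± 6.65 CPM with FGF-2, those of adrenal medulla to 6.57 ± 0.81 and 2.94 ± 0.93 CPM, and those of endothelium and blood to 14.2 ± 3.65 and 12.2 ± 1.27 CPM. Col6a1, which led the first of these, had a log2 fold change of -0.39 and did not pass (edgeR Benjamini-Hochberg adjusted p = 0.0891), but passed without serum library 1 (-0.58) and with upper-quartile (-0.53) or library-total scaling (-0.72). Ddc of the medulla markers and Pecam1 of the endothelium markers fell (edgeR Benjamini-Hochberg adjusted p = 0.000901 and 0.0296). The call of Pecam1, with a log2 fold change of -0.93, was lost without serum library 2, FGF-2 library 2 or FGF-2 library 3, where the values were -0.59, -0.95 and -0.79. Over the settings fixed in advance, which included edgeR, DESeq2 and limma, its Benjamini-Hochberg adjusted p lay between 0.0159 and 0.162. The division into higher and lower genes depended on scaling: 47.7% of the called genes were higher with TMM, 32.7% with upper-quartile scaling (1616 higher, 3320 lower) and 18.1% with library totals alone (1035 higher, 4675 lower), as the median log2 fold change of all tested genes went from -0.023 to -0.16 and -0.36. None of the 11 lists called with the preset correlation was called with an estimated correlation. Other divisions of the 6 libraries into 3 and 3 called up to 16 lists, but these divisions keep part of the treatment difference. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between libraries, which may be technical.

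The authors' deposited table of DESeq2 results called 2385 genes higher and 2140 lower. Of its 4525 calls, 4287 were also called by edgeR, all in the same direction, and the log2 fold changes had a Pearson r of 1.00 and a Spearman rho of 1.00 across 10374 genes, which are not independent replicates.

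H3K27ac rose at many more regions than it fell in the authors' deposited table. Of 40772 regions there, 3398 were higher and 670 lower with FGF-2 at a false discovery rate of 0.05. In the authors' deposited table, 2999 of 26341 regions away from promoters were higher and 559 lower, and of 14431 promoter regions 399 were higher and 111 lower. At a region 13066 bases downstream of the start of Dusp5 (mm10 chromosome 19, 53542384 to 53546513), the authors' deposited table gives 79.2 and 92.8 normalised reads in the serum libraries and 496 and 424 in the FGF-2 libraries. A region at -75936 bases from the start of Spred2 (chromosome 11, 19847637 to 19848506) had a log2 fold of 2.74 in the authors' deposited table, with 21.2 and 11.7 against 119 and 101 normalised reads.

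Of 116 regions tied to ERK feedback regulators, 39 were higher and 2 lower in the authors' deposited table, including regions at Dusp4 and Errfi1 with log2 folds of 2.01 and 2.67. A gene can hold several regions, and the higher ones lay at 8 of 15 genes. Of 126 regions tied to immediate-early genes, 8 were higher and 3 lower in the authors' deposited table. That share of higher regions was below the 8.33% of all regions in the authors' deposited table, where a promoter region of Ier3 had a log2 fold of 2.32. Smaller values in the authors' deposited table were 1.18 at Btg2 and 0.71 at the promoter of Klf6, and a region near Fosb had 2.06. Of 90 regions tied to steroidogenic genes, 16 were higher and 3 lower in the authors' deposited table, the higher ones at 6 of 15 genes. An intronic region whose nearest gene was Mc2r, the ACTH receptor gene, at -99674 bases from its start (chromosome 18, 68528994 to 68530348), had 6.45 and 8.36 against 71.3 and 76 normalised reads in the authors' deposited table, and regions at Scarb1, Cyp11a1 and Por had log2 folds of 1.13, 3.11 and 1.53 there. Of these genes Por rose in RNA, from 1419 ± 434 to 3680 ± 250 CPM, Scarb1 had 242 ± 33.5 and 252 ± 61.6 CPM, and the RNA of Cyp11a1 was lower. Of 62 regions tied to G2/M genes, 0 were higher and 3 lower in the authors' deposited table.

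The 5 highest folds in the authors' deposited table, between 6.40 and 6.81 on the log2 scale, were nearest to Ints13, Rai1, B930018H19Rik and, for a pair of regions, Egflam. Each had both serum libraries at the table's floor of 1 read, so these folds depend on that floor. The Ints13 region (chromosome 6, 146550659 to 146551277) also lay in a stretch of high input background. Of the 5 lowest in the authors' deposited table, those near Gm19990, D030025E07Rik, Pdcd1lg2 and Mllt3 had both FGF-2 libraries at the floor. The fifth, an exonic region nearest to Nfasc (chromosome 1, 132594921 to 132596424), had 116 and 89.4 normalised reads with serum alone and 2.85 and 6 with FGF-2 in the authors' deposited table, and Nfasc RNA had a log2 fold change of -3.02 ± 0.24.

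The excess of gains depended on scaling and on single libraries. Of the regions called in the authors' deposited table, 83.5% were higher. With edgeR on the reads recovered from its values the share was 77.6% with library totals (5118 higher, 1475 lower) and 63.9% with TMM scaling (4436 higher, 2501 lower). With library totals edgeR called 6264 and 790 without serum library 1, 4439 and 2663 without serum library 2, 1969 and 432 without FGF-2 library 1, and 3224 and 522 without FGF-2 library 2.

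Peaks called per library gave 44340 and 41975 peaks for serum alone and 50317 and 46712 for FGF-2, by the authors' caller. A total of 3965 merged regions were found in both FGF-2 libraries and neither serum library, and 2095 in both serum libraries and neither FGF-2 library. Pairs of 1 serum and 1 FGF-2 library shared between 363 and 1034 regions that the other pair lacked. With equal numbers of top peaks per library the counts were 2861 and 2787. Equal numbers of peaks by themselves draw the counts of the 2 groups together, so this does not show whether the excess is real. Without serum library 1, serum library 2, FGF-2 library 1 or FGF-2 library 2 in turn, the counts for FGF-2 were 5714, 5318, 7352 and 11072, and those for serum 4620, 7467, 3724 and 3307, since 1 library of a group then suffices. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, and these counts of peak regions were not tested.

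Transcript and H3K27ac changes went together across genes. Of 9208 tested genes with a region, 548 had both higher RNA and a higher region where 254 would be expected from independent calls, an odds ratio of 4.04 with a 95% interval of 3.54 to 4.60 (two-sided Fisher's exact test, p = 3.09e-95, Benjamini-Hochberg adjusted p = 1.24e-94). For lower calls the number was 168 against 92.9, an odds ratio of 2.59 with an interval of 2.09 to 3.22 (two-sided Fisher's exact test, p = 6.86e-18, Benjamini-Hochberg adjusted p = 9.15e-18). Region calls came from the authors' deposited table, genes are not independent replicates, and 4 such overlaps were tested. Both calls in opposite directions were rarer than expected from independent calls, with odds ratios of 0.540 for higher RNA with a lower region and 0.391 for lower RNA with a higher region (two-sided Fisher's exact test, p = 1.94e-05 and p = 2.25e-28, Benjamini-Hochberg adjusted p = 1.94e-05 and 4.5e-28). Each was compared with all other genes, including those whose RNA changed the same way as the region. These ratios therefore partly restate the overlaps above, and no comparison with uncalled genes alone was run. The genes of smallest edgeR p that were higher in both were Spred2, Smad3, Sik1, Lbh, Slc41a1 and Wfs1. Smad3, a mediator of TGF-beta signalling, went from 38.3 ± 3.58 to 161 ± 7.83 CPM, and an intronic region had a log2 fold of 0.95 in the authors' deposited table. Lbh went from 80 ± 13.4 to 691 ± 108 CPM, and a region had a log2 fold of 2.36 in the authors' deposited table. Those lower in both were Pde5a, Fam46b, St5, Olfml2b, Aspm and Fam65b. The promoter region of Aspm, a spindle gene, had a log2 fold of -1.33 in the authors' deposited table, and Aspm RNA went from 78.3 ± 4.13 to 18.2 ± 2.87 CPM. Rtn4rl1 rose in RNA while an intronic region nearest to it was lower, and Akap6, Plekha7 and Tmem94 fell while a region was higher. In the authors' deposited table both serum libraries were at the floor for the Akap6 region and serum library 2 was for the Plekha7 region.

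The RNA log2 fold change correlated across genes with the fold of the promoter region in the authors' deposited table (Pearson r = 0.418, Spearman rho = 0.353, 8574 genes) and with the mean fold of other regions (r = 0.358, rho = 0.310, 4778 genes). Each had a permutation p of 1e-05, the smallest that 100000 resamples can give, and the adjusted values of these 2 relations were also 1e-05.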

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

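The tests of mixed RNA, of depth, of floored regions, of the share of gains and of other groupings of the RNA libraries by gene counts were chosen after the results were seen.

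The background at peaks, computed as the authors' pileup plus 1 over their fold, stood far above the rest of the genome over 3 bins of 1 megabase on chromosome 6 and 1 unplaced contig. It is given here because the input signal was not itself compared between groups, although the authors' peak calls used it as background. Its median at the peaks there was 13.3 and 14.3 times the library median for serum alone and 12.5 and 11.2 times for FGF-2. Copy number was not measured here. Regions there were called changed more often, with an odds ratio of 3.83 (95% interval 2.72 to 5.33). Within 10 strata of mean normalised reads in the authors' deposited table, the odds ratio was 3.83 (2.77 to 5.30). If input reads were subtracted from those values, the strata do not match raw reads, so the number of raw reads stays open. A group left at the floor by subtraction of many input reads, which is not stated for the table, does not account for the excess alone. Among regions with no group at the floor, 46 of 170 there were called against 3735 of 40269 elsewhere, an odds ratio of 3.63 (2.52 to 5.14). These intervals take neighbouring regions as independent, which a change shared along the stretch would break. An effect of such subtraction above the floor was not tested and stays open.

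Serum RNA library 3 lay toward the FGF-2 libraries, at -29.5 on the first principal component where the other serum libraries were at -52.4 and -50.6, and on the second component it lay with FGF-2 library 3, at -20.8 and -20.1 where the other libraries were between 5.54 and 15.6 (the deviations of these 2 libraries had a correlation of 0.38). RNA of an FGF-2 sample mixed into it would give 1 share for all genes, and of 40 genes that rose at least 16-fold without it only 40% lay within 3 points of their median share of 7.03%. Dll4 lay at 1.09%, and 498 genes that fell had a median share of 29.7%, so no single share was seen. Shares were taken of the mean FGF-2 level, and the 3 points allow nothing for counting error, so mixing was not excluded. Fewer reads alone give fewer counts, and the ratio of totals was 0.652. Yet the counts of serum library 3 for the 40 genes that rose were a median of 2 times the mean counts of the deeper serum libraries (quartiles 1.37 and 5.83). For 34 of them its counts were above those of each deeper serum library. Both sets of genes were picked by their levels in those deeper libraries, which by itself favours values in library 3 nearer to FGF-2. Even so, serum library 3 had 1080 counts of Inhba and 1694 of Star. The deeper serum libraries had 75 and 103 of Inhba, and 1015 and 1102 of Star. Counts above those of deeper libraries argue against depth alone for the 34 genes. For the rest of the library depth was not excluded. A difference shared by both libraries numbered 3, or particular to serum library 3, was not tested and stays open.

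More regions gained than lost H3K27ac, and serum library 2 had the lowest share of its fragments in regions, 28%. Scaling by library totals could then favour gains. With edgeR 77.6% of changes were gains with library totals and 63.9% with TMM scaling, and 62.5% with library totals but without that library. With TMM scaling and a single library left out the share lay between 59.3% (without FGF-2 library 1) and 65.9%. All of these lay above the 45% to 55% that would be seen if scaling were the whole source, but the lowest missed the bound of 60% set for excluding it, so scaling and a real excess cannot be told apart.

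With 10 ways to divide the 6 RNA libraries into 3 and 3, no share under 0.05 can be reached. The real division called 4807 genes in edgeR, and the highest of the others called 0 (5 to 248 genes at an unadjusted p under 0.05). For gene lists the real division called 11, and the highest of the others 16. In all, 4 of the 10 divisions, the real one included, called 11 or more. Each other division kept part of the treatment difference between its sides and put the rest into the spread within them. The 0 genes and 16 lists are therefore no measure of calls without a treatment effect.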

How the results depend on the processing

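Upper-quartile and library-total scaling, the counts of list members without single libraries and all retests of H3K27ac regions were chosen after seeing the data, and the causes of the changes below were not tested except where named. RNA calls numbered 4807, with 1647 at an absolute log2 fold change of at least 1 (707 higher, 940 lower) and 3059 at a false discovery rate of 0.01, both narrower by construction. Library totals alone gave 1035 higher and 4675 lower. The other RNA settings kept each count within 1.5 times, and leaving out single libraries gave 3516 to 4957 calls. Gene lists called higher and lower went from 8 and 3 to 0 and 0 with an estimated correlation, to 11 and 7 with fry, and to 7 to 12 and 3 to 5 without single libraries, the 5 without FGF-2 library 3.

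Of 1638 values for 117 named genes under other settings, 1563 kept direction and side of the threshold, 66 lost a call, 4 gained one and 5 changed sign without a call in either. These were Fgfr1 (-0.16 with library totals), Ccnd1 (-0.084 with upper-quartile scaling, -0.28 with library totals) and Nr5a1 (-0.17 to 0.048 without single libraries). Of 112 called genes, 17 lost the call in a planned setting. Of 286 list values, 253 kept direction and side, 12 were weaker and 16 stronger. The test of FGF receptors and co-receptors turned direction, uncalled, with fry (median -0.071) and without single libraries (medians -0.16 to 0.025), and that of cholesterol genes without single libraries (-0.051 to 0.23).

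Same-numbered RNA libraries deviated together with correlations of -0.10, 0.07 and 0.38, and 2 of 6 libraries correlated best with their own number, so the numbers were not taken to pair the samples. A replicate block gave 5017 RNA calls (2375 higher, 2642 lower). For H3K27ac, whose same-numbered libraries had a correlation of -0.33, a block gave 3862 higher and 852 lower, and a crossed block, chosen after seeing the data, 6102 and 2091.

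H3K27ac regions higher and lower, 3398 and 670 in the authors' deposited table, were 2099 and 297 at a false discovery rate of 0.01, 4333 and 1047 at 0.1, 5118 and 1475 with edgeR on recovered reads, 4436 and 2501 with TMM, and 5155 and 1551 with limma. Leaving out single libraries gave 1969 (without FGF-2 library 1) to 6264 (without serum library 1) higher and 432 (without FGF-2 library 1) to 2663 (without serum library 2) lower, where the lone library of a group is assumed to vary like the others. With TMM they were 3286 and 1745 without serum library 1, 4616 and 2391 without serum library 2, 2869 and 1971 without FGF-2 library 1, and 3933 and 2148 without FGF-2 library 2. Leaving out floored regions (3124, 657) or high-background regions (3361, 654) changed little. Regions specific to FGF-2 or serum, 3965 and 2095, were 5461 and 3457 at 50% reciprocal overlap, 3108 and 1857 at a stricter peak q, and 5318 to 11072 and 3307 to 7467 without single libraries, where 1 library of a group then suffices by construction. Links between RNA and H3K27ac kept direction and side of the threshold in all planned settings, with odds ratios of 3.66 to 6.08 for higher and 1.84 to 9.65 for lower calls and r from 0.321 to 0.421. Promoter regions all lay within 10 kb, so that setting moved nothing there. Leaving out mitochondrially encoded genes was not run, since the tables hold none. In simulated regions edgeR recovered 15% of 2-fold changes, so changes of that size can go uncalled by edgeR.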

Other observations

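The tests of BMP-SMAD and FOXO targets were chosen after the results were seen.

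Lists outside the main account did not pass camera, with Benjamini-Hochberg adjusted p between 0.088 and 0.708. With fry, which tests whether the members of a list move one way on balance and does not compare them with other genes, 5 of them passed. These were histone acetylation (adjusted p = 0.0043), YAP and SRF (0.0245) and p53 (0.033), all down, and NRF2 (0.0439) and glycolysis (0.0498), both up. Members that rose and fell adjusted over the list alone numbered 5 and 0 for NRF2 targets, 9 and 3 for matrix and adhesion, 3 and 9 for YAP and SRF, 4 and 7 for p53 and 4 and 6 for histone acetylation. They numbered 6 and 6 for cholesterol, 2 and 0 for glycolysis, 1 and 2 for interferon, 4 and 0 for ER chaperones, 5 and 2 for ATF4 and 3 and 2 for heat shock. Of 13 NRF2 targets 5 rose and 0 fell, led by Srxn1, which reduces oxidised peroxiredoxins, from 147 ± 80 to 2460 ± 593 CPM, and Osgin1. With library totals alone 3 of them rose and 5 fell. Of 22 extracellular matrix and adhesion genes 9 rose and 2 fell. The integrin gene Itgb3 and the tenascin gene Tnc rose, with log2 fold changes of 3.94 ± 0.65 and 3.47 ± 0.72, which were 5.06 and 4.79 without serum library 3. Col3a1 and Loxl2 had values of -0.46 and -0.43, calls that were lost without any 1 of serum libraries 1 and 3 and FGF-2 libraries 1 and 3. Of 21 YAP, SRF and actin genes 3 rose and 9 fell, with Filip1l at -2.53 ± 0.14, Ajuba at -1.22 ± 0.26 and Tagln2 at 0.79 ± 0.10. Of 16 p53 targets 3 rose and 7 fell, with Trp53inp1 at -2.39 ± 0.17 and Gtse1 at -2.30 ± 0.17 against Cdkn1a at 2.19 ± 0.33, and without serum library 3 they became 6 and 7. Of 22 histone acetylation genes 4 rose and 6 fell, with Hdac9 at -2.27 ± 0.20 and Hdac7 at -1.23 ± 0.11 and with Brd2 at 0.58. The median of that list was 0.030 and its mean -0.17, and with library totals alone 0 of its members rose and 9 fell. Other counts also moved with single libraries: 3 NRF2 targets rose without serum library 2 and 1 fell without FGF-2 library 3, 1 YAP and SRF gene rose without serum library 1, and 2 histone acetylation genes rose without serum library 1 or 2. Without serum library 1, serum library 3 or FGF-2 library 3, 0 matrix and adhesion genes fell, and 1 did without FGF-2 library 1.

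Of 23 cholesterol genes 6 rose and 6 fell, and 4 rose and 10 fell with library totals alone. Msmo1 rose by 1.06 ± 0.24 on the log2 scale, while Mvk and Mvd had -1.09 ± 0.13 and -0.71 ± 0.15. Of 14 genes of glycolysis 3 rose and 1 fell (2 and 4 with library totals alone, 2 and 2 without serum library 3, and 2 and 0 without serum library 2, FGF-2 library 1 or FGF-2 library 3), and the glucose transporter gene Slc2a1 and Pfkfb3 had 2.17 ± 0.16 and 1.75 ± 0.13. Of 12 interferon-stimulated genes 1 rose and 3 fell, with Isg15 at 1.21 ± 0.14 and Stat2 at -0.99 ± 0.16. Stress lists gave 5 up and 0 down of 19 for ER chaperones (Dnajb9 at 1.31 ± 0.14), 5 up and 2 down of 19 for ATF4 targets (Slc7a5 at 0.88 ± 0.20) and 3 up and 2 down of 15 for heat shock (Hsp90aa1 at 0.75 ± 0.14). With library totals alone these became 2 and 4, 1 and 5, and 2 and 3, and without serum library 3 ATF4 targets became 10 and 2. Without serum library 1 the ATF4 targets became 1 and 1, without serum library 2 they became 1 and 2, and without FGF-2 library 1 or 3 they became 3 and 1. ER chaperones that rose were 3 without serum library 1 or 2, and heat shock genes became 5 and 1 without FGF-2 library 2 and 2 and 1 without serum library 2.

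Smad6 and Atoh8 were among the largest decreases, which suggested a fall of BMP-SMAD targets as a hypothesis. The test left it open: of 9 other measured targets 2 rose and 4 fell. The list did not pass (camera p = 0.565, and p = 0.582 with an estimated correlation). Its median log2 fold change was -0.17. With library totals alone it was -0.52, where the median of all tested genes was -0.36. Smad9, Id3, Acvrl1 and Smurf1 fell, at -2.18 ± 0.29, -1.89 ± 0.24, -1.04 ± 0.20 and -0.42 ± 0.12, while Smad7 and Runx2 rose, at 0.78 ± 0.12 and 1.75 ± 0.16.

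Txnip, Sesn1, Rbl2 and Trp53inp1 fell, with log2 fold changes of -3.03, -1.82, -1.37 and -2.39, which suggested lower FOXO target expression as a second hypothesis. It stays open too: of 18 other measured targets 4 rose and 4 fell (camera p = 0.746, and p = 0.864 with an estimated correlation). Their median was -0.12, although the direction of the camera test was up. With library totals alone their median was -0.46, where that of all tested genes was -0.36. Ccng2, Gabarapl1, Bcl2l11 and Rictor rose, at 3.16 ± 0.49, 1.02 ± 0.13, 0.88 ± 0.12 and 0.46 ± 0.11, and Pik3ip1, Fbxo32, Foxo3 and Cat fell, at -1.58 ± 0.23, -1.41 ± 0.49, -0.71 ± 0.18 and -0.66 ± 0.19.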
